A study of Homo sapiens with 6 samples.

How the data were processed

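Expression was measured in 6 samples of total RNA from 2 human breast cancer cell lines, 3 from SUM44 and 3 from LCCTam, each hybridized to its own Affymetrix array with 22283 probe sets. The RNA was biotin-labelled by a one-cycle protocol, per the labels' protocols. The deposited values are log2 expression values that the authors made with RMA as implemented in Bioconductor, per the submitters' processing notes and design text. RMA corrects background, makes the distributions of arrays alike and summarises the probes of a probe set. The version, the chip definition and whether all 6 arrays were processed together are not given in the sources used here. The values held no detection calls, so the level that stands for no expression is unknown, and differences of dim genes can be compressed. The number of arrays limits the precision.

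Samples were grouped by the line in their titles. The titles also gave passages, 74 to 76 for SUM44 and 8 to 10 for LCCTam, which were used as replicate numbers 1 to 3. The lines share no passage, so samples were not paired. Nothing in the labels says that the passages of a line were independent cultures, so the p-values measure the spread between these samples. Scan dates were not used here, so a difference in array batch and a difference between lines cannot be told apart.

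Probe sets were named from the platform annotation given with the data. Of the probe sets, 68 were controls, 20114 were listed in that annotation and 2107 others were not, and are unnamed here. Of the controls, 6 were also listed with a symbol, so they count among both and were left out of all fits. Of the listed probe sets, 19071 had 1 gene symbol and 1043 had several, and none was named from the latter. Symbols of 19059 probe sets were updated through their Entrez identifiers with the RefSeq gene table of assembly GRCh38.p14. The probe set with the highest mean over the 6 arrays stood for each gene, which gave 11963 genes, of which 4310 had several probe sets. In a separate fit of 19065 named probe sets, 1405 passed, and 0 genes had probe sets passing in opposite directions.

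Differences are LCCTam minus SUM44 on the log2 scale. They were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no intensity filter), and p-values were adjusted by the Benjamini-Hochberg method. An adjusted p under 0.05 counted as passing, and all adjusted p-values of genes come from this fit unless another is named. The prior degrees of freedom were 3.12. Further counts were made from the same fit. One added an absolute log2 difference of at least 1. The other followed the selection in the submitters' design text, at least a 2-fold change, an unadjusted p under 0.05 and a mean of at least log2 of 10 in both lines. That text names no test, so limma's p was used. The intensity floor removed 0 genes.

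Before the data were examined, 27 gene lists were fixed with 838 different genes, of which 724 were measured. They covered estrogen receptor targets, nuclear receptors and their coregulators, oxidative phosphorylation and the TCA cycle, AP-1 factors and AP-1 responsive genes, luminal, basal and mesenchymal markers, epithelial adhesion, proliferation, growth factor receptors and ligands, 8p11-p12 genes, cholesterol and fatty acid synthesis, interferon-stimulated genes, antigen presentation, the unfolded protein response, apoptosis, p53 targets, NF-kappaB, hypoxia and glycolysis, drug metabolism, WNT, ribosomal proteins, and fibroblast and leukocyte or endothelial markers. Each was tested against all other genes with limma's camera at a preset correlation of 0.01, adjusted over the 27 lists. Camera with an estimated correlation, fry and 10000 random lists matched on mean expression were alternatives. Members were also adjusted over the list alone.

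The genes named were fixed by rule before the data were examined. The rule took ESRRG, ESR1 and PGR, the 10 genes with the largest positive and the 10 with the largest negative difference among passing genes whose values in the lines did not overlap, and up to 4 passing members with the largest absolute differences per list. A list with no passing member gave the member with the largest difference, as a value. Other genes named in the text were chosen after their values were seen.

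The fit was tested on simulated data for LCCTam against SUM44, with 11963 genes and 50 changed genes at each of 4 sizes. It recovered 20% of those changed by 0.5 on the log2 scale, 82% at 1, 96% at 2 and 100% at 3. Of its 164 calls 15 were false, which is 9.15%. Of 200 unchanged lists 0 were called, and the shifted list was found. The simulated genes were drawn independently, so this does not test the list test where list members are correlated. No effect shared by the genes of an array was simulated, and fewer genes were changed than passed in the real fit. The shares recovered and false may therefore differ in the real data.

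Alternatives fixed before the data were examined changed the treatment of several probe sets per gene, the probe sets with suffixes _x_at and _s_at, which can match several transcripts, the intensity filter, the variance moderation, array weights, the scaling between arrays and the thresholds. Passage centred within each line was added as a covariate, and each array was left out in turn. Quantile normalization between arrays was added after seeing the data, as was the closer look at results without LCCTam replicate 3. Figures were drawn with matplotlib.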

Results

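The data compare SUM44, a line from an invasive lobular breast carcinoma that the labels describe as positive for estrogen and progesterone receptors, with LCCTam, its tamoxifen-resistant variant. The series title names the estrogen-related receptor ERRγ, the product of ESRRG, as the subject of the study. SUM44 was sampled at passages 74, 75 and 76 and LCCTam at passages 8, 9 and 10. Per the labels' protocols, LCCTam was grown with 500 nM 4-hydroxytamoxifen and SUM44 without it, so the line and the presence of the drug cannot be separated. The median log2 expression was between 5.92 and 5.97 on all 6 arrays. Pearson's r across genes was 0.986 to 0.994 within SUM44, 0.985 to 0.996 within LCCTam and 0.967 to 0.979 between the lines. LCCTam replicate 3 stood apart in its actin and GAPDH controls and in its 75th percentile. Its actin control probe sets had a 3' minus 5' difference of 1.92, against 0.90 to 1.15 on the other 5 arrays. For GAPDH the difference was 0.61, against 0.09 to 0.31, and the 75th percentile of expression was 7.50, against 7.68 to 7.78.

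ESRRG, an orphan nuclear receptor related to the estrogen receptors, was higher in LCCTam, and ESR1, which encodes estrogen receptor alpha, was lower. The brighter of the 2 ESRRG probe sets had a log2 expression of 7.02 ± 0.08 in SUM44 and 9.11 ± 0.48 in LCCTam (SD, n = 3 each). The difference was 2.10 (SE 0.22, limma adjusted p = 0.00333), or 4.28-fold. The other ESRRG probe set was 1.19 higher (2.28-fold, adjusted p = 0.0179 in the fit of all probe sets). Every LCCTam value lay above every SUM44 value for both probe sets. Without LCCTam replicate 3 the ESRRG difference was 1.88 (adjusted p = 0.00418).

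The brightest ESR1 probe set was 12.74 ± 0.23 in SUM44 and 11.08 ± 0.13 in LCCTam (SD, n = 3 each), a difference of -1.65 (SE 0.14, adjusted p = 0.00124), or 3.15-fold lower. Of the 9 ESR1 probe sets 5 passed, all 5 of them lower. PGR, the progesterone receptor gene and a target of estrogen receptor alpha, was read by 1 probe set, at 3.85 ± 0.05 in SUM44 and 3.85 ± 0.01 in LCCTam (SD, n = 3 each; adjusted p = 0.991). These means were low, at percentile 5.47 of all probe sets in SUM44 and 5.31 in LCCTam. The background is unknown, so these values do not tell whether PGR was expressed, and a difference at low PGR levels was not detectable here.

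**Figure D1:**
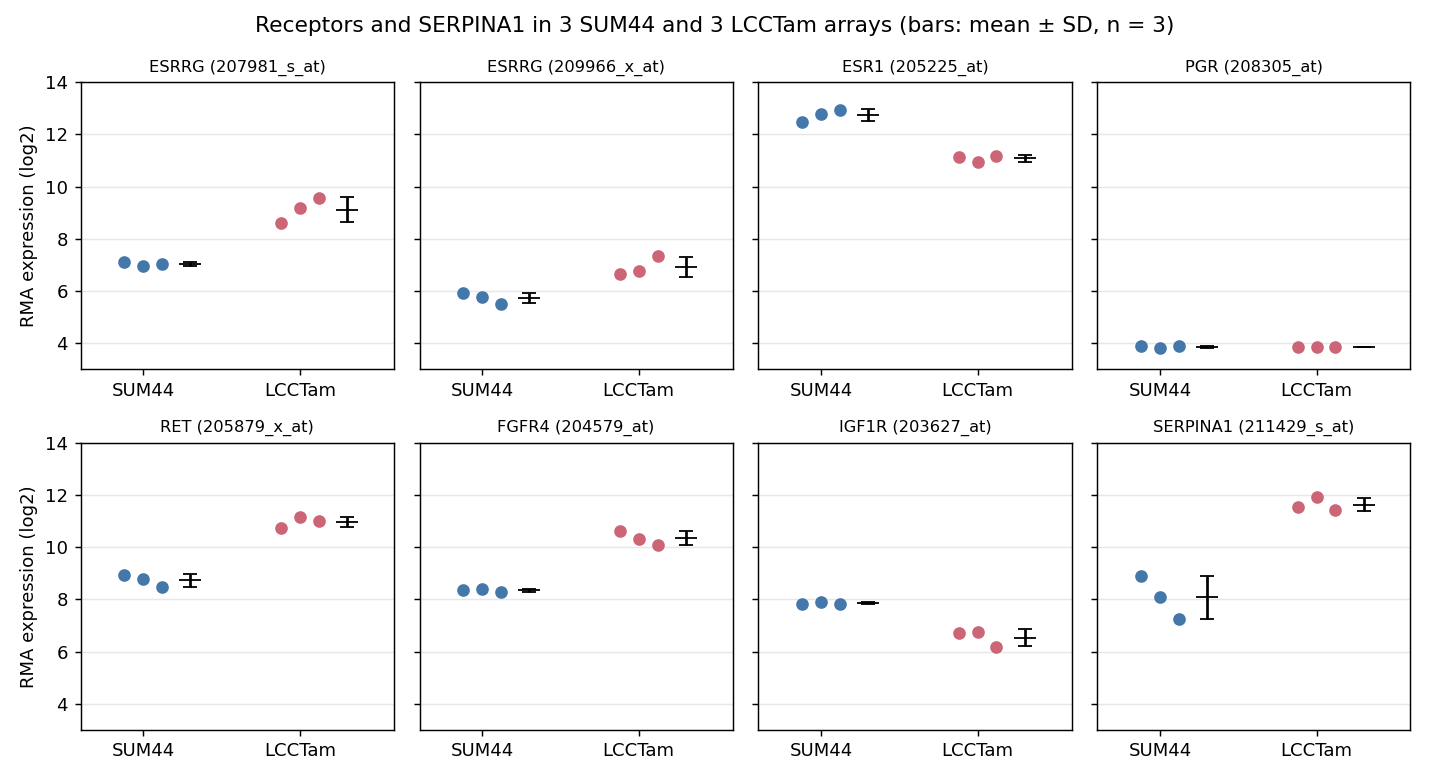
Log2 RMA expression of ESRRG, ESR1, PGR, RET, FGFR4, IGF1R and SERPINA1 in 3 SUM44 and 3 LCCTam arrays, with the probe set in each panel title. Points are arrays and bars are the mean ± SD. Both ESRRG probe sets were higher in all 3 LCCTam arrays, ESR1 was lower in all 3, and PGR was 3.85 on average in both lines.

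Among the genes that passed, more were lower than higher in LCCTam, while the median difference of all genes was 0.017. Of 11963 genes tested, 948 passed an adjusted p of 0.05, 250 higher and 698 lower in LCCTam, so 73.6% were lower. With at least a 2-fold change 255 passed, 65 higher and 190 lower. The selection in the submitters' design text took 294 genes, 72 higher and 222 lower. The values of the lines did not overlap for 3570 genes, or 29.8%, where chance gives 10%, and 55.7% of these were lower. The counts depended on single arrays. Leaving out LCCTam replicate 3 gave 1527 genes, 633 higher and 894 lower (58.5% lower), and 887 of the 948 passed again in the same direction. Leaving out SUM44 replicate 2 gave 259 genes (157 of them 2-fold), leaving out LCCTam replicate 1 gave 353 and leaving out LCCTam replicate 2 gave 401. With quantile normalization between arrays 54.2% of the passing genes were lower, and with array weights 50.6%. In the weighted fit LCCTam replicate 1 and SUM44 replicate 2 counted most, at weights of 4.02 and 2.88.

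LRRC15 and ADCY1 had the largest increases. LRRC15, a leucine-rich repeat membrane protein, rose by 4.76 on the log2 scale, from 6.80 ± 0.38 to 11.56 ± 0.22 (SD, n = 3 each; adjusted p = 0.00013). ADCY1, an adenylyl cyclase that makes cyclic AMP, rose by 4.58 (adjusted p = 0.000121), and SPINK4, a secreted protease inhibitor, by 4.33. LRP4, a receptor of the LDL receptor family, rose by 3.71, SERPINA1, which encodes alpha-1 antitrypsin, by 3.55, and LAMA4, a laminin chain, by 3.23. SYNPO2L rose by 2.88, AMBP by 2.70, the phosphatase gene PTP4A1 by 2.55 and NDST4, an enzyme of heparan sulfate synthesis, by 2.35. SERPINA1 and AMBP varied among the SUM44 samples, at 8.91, 8.09 and 7.26 and at 10.51, 9.21 and 8.45 in replicates 1 to 3.

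The largest decreases were in COL3A1, a fibrillar collagen, and GJA1, the gap junction protein connexin 43. COL3A1 went from 8.64 ± 0.37 to 4.22 ± 0.21 (SD, n = 3 each), a difference of -4.42 (adjusted p = 0.000158). GJA1 went from 9.48 ± 0.09 to 5.44 ± 0.76 (difference -4.03, adjusted p = 0.00137). The interferon-stimulated gene IFI27 differed by -3.97, the apolipoprotein gene APOD by -3.83, TACC1 by -3.77 and ALB, which encodes albumin, by -3.72. The aldo-keto reductases AKR1C2 and AKR1C1 differed by -3.52 and -3.30, and the similar sequences of these 2 genes can cross-hybridize. SCGB2A2, which encodes mammaglobin, differed by -3.36 and AZGP1 by -3.29. SCGB2A2 had an adjusted p of 0.0436, and of 0.0697 without LCCTam replicate 3. Several of these genes fell over SUM44 replicates 1 to 3, TACC1 at 10.68, 10.43 and 8.71, APOD at 11.64, 10.41 and 9.00, AKR1C2 at 13.77, 12.47 and 11.09, AKR1C1 at 13.70, 12.41 and 11.03, and SCGB2A2 at 13.08, 12.22 and 10.24. The size of their differences therefore depends on the SUM44 sample. For COL3A1, TACC1 and ALB, the probe sets left after those with the suffixes _x_at and _s_at were removed differed by 0.02, 0.09 and 0.03.

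Interferon-stimulated genes formed the list with the clearest shift, and it was downward. Of 42 measured genes 0 rose, 16 fell and 26 did not pass, and 29 fell when adjusted over the list alone. The median difference was -0.70 (camera adjusted p = 2.2e-13), with adjusted p = 0.397 with an estimated correlation. IFI27 fell by 3.97 on the log2 scale. IFITM3, a membrane protein that restricts virus entry, went from 10.12 ± 0.05 to 7.12 ± 0.36 (SD, n = 3 each), and the related IFITM2 differed by -2.18. The IFITM2 and IFITM3 probe sets carry the suffix _x_at and can cross-hybridize. ISG15, a ubiquitin-like protein, went from 10.50 ± 0.36 to 8.33 ± 0.44 (SD, n = 3 each), and IRF9, the DNA-binding part of the ISGF3 transcription factor, from 9.17 ± 0.31 to 7.11 ± 0.55. Without LCCTam replicate 3, the array with the stronger 3' minus 5' difference, the list's median was -0.55 (camera adjusted p = 1.4e-11).

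**Figure D2:**
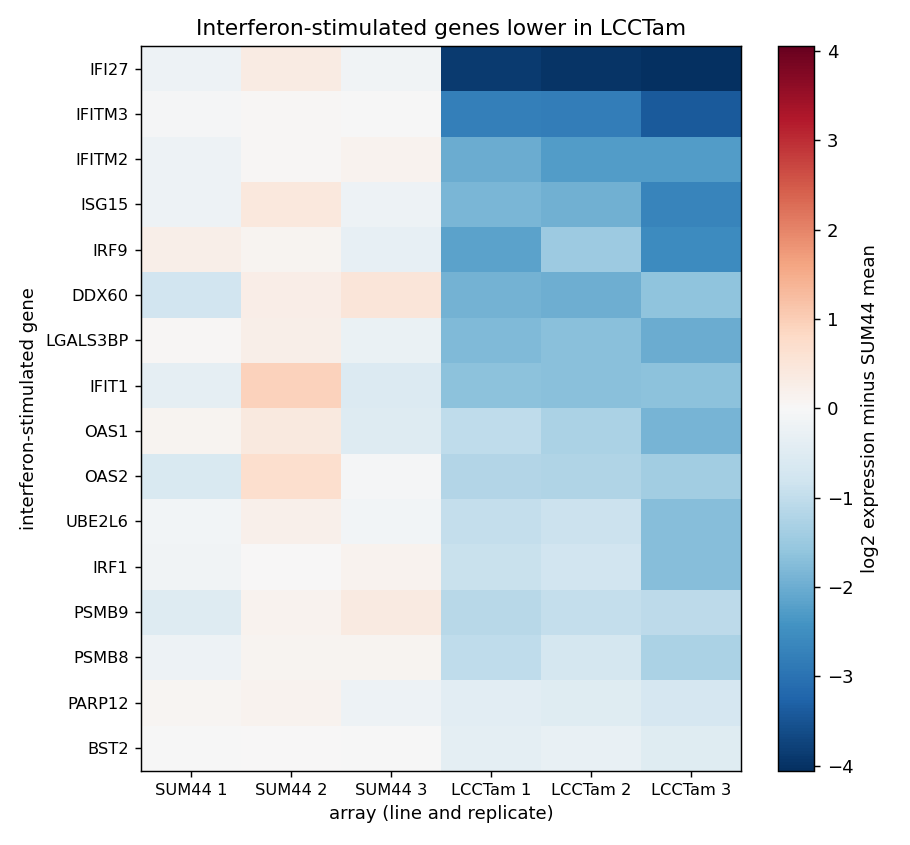
Log2 expression minus the SUM44 mean for the 16 interferon-stimulated genes that were lower in LCCTam, one gene per line of the heat map and one array per column. Blue is lower and red is higher than the SUM44 mean, and all 3 LCCTam arrays were lower than all SUM44 arrays for each gene.

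Antigen presentation genes as a list were not shifted (22 measured, 0 higher, 5 lower, 7 lower when adjusted over the list alone; median -0.10, and -0.017 without LCCTam replicate 3; camera adjusted p = 0.198). The immunoproteasome subunits PSMB9 and PSMB8 differed by -1.04 and -1.0, and the MHC class I genes HLA-C and HLA-B by -0.76 and -0.74. The HLA-C and HLA-B probe sets carry the suffix _x_at and can cross-hybridize. Without LCCTam replicate 3 the adjusted p of PSMB9 was 0.0539. Of 26 measured NF-kappaB genes 0 rose and 2 fell, likewise 2 when adjusted over the list alone (camera adjusted p = 0.51). They were IRF1, an interferon-responsive factor, at -1.14, and NFKBIA, the inhibitor of NF-kappaB, at -0.57.

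Estrogen receptor targets went both ways. Of 37 measured, 8 rose, 6 fell and 23 did not pass, with 8 and 10 when adjusted over the list alone, and the list as a whole was not shifted (median -0.04, camera adjusted p = 0.833). With LCCTam replicate 3 left out, 8 were higher and 8 lower, with a median of -0.020. SERPINA1 rose by 3.55, RET, a receptor tyrosine kinase, by 2.25 (adjusted p = 0.000686) and KRT13 by 1.97. IL17RB, an interleukin receptor, fell by 1.99 on the log2 scale, from 9.94 ± 0.44 to 7.94 ± 0.21 (SD, n = 3 each). Nuclear receptors numbered 39, of which 1 rose and 3 fell, with 1 and 5 when adjusted over the list alone (camera adjusted p = 0.833). Beside ESRRG and ESR1, the mineralocorticoid receptor gene NR3C2 differed by -1.0 and NR1D2, a receptor of the circadian clock, by -0.91. Of 25 coregulators 0 rose and 6 fell, 8 when adjusted over the list alone (median -0.15, camera adjusted p = 0.063). TRIM24 differed by -0.92, the corepressor gene NRIP1 by -0.82, the coactivator gene NCOA2 by -0.76 and TLE1 by -0.59. The coregulator median was 0.01 without LCCTam replicate 3, with 1 higher and 8 lower, and 2 nuclear receptors were higher and 3 lower. The other TRIM24 probe set, left after those with the suffixes _x_at and _s_at were removed, differed by 0.05.

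Luminal markers were shifted downward. Of 23 measured, 0 rose and 5 fell, 6 when adjusted over the list alone, with a median of -0.23 (camera adjusted p = 0.0109). The camera adjusted p was 0.605 with an estimated correlation, and it was 0.118 without LCCTam replicate 3. Without that array 3 were lower and the median was -0.13. Without the _x_at and _s_at probe sets the list was not shifted. SCGB2A2 differed by -3.36, SCNN1A, a subunit of the epithelial sodium channel, by -2.87, ESR1 by -1.65 and the trefoil factor gene TFF1 by -1.46. Basal markers were not shifted (18 measured, 0 higher, 2 lower, 2 lower when adjusted over the list alone; camera adjusted p = 0.833). CDH3, which encodes P-cadherin, differed by -1.69 and the integrin gene ITGB4 by -0.84, while the ITGB4 probe set left without the suffixes _x_at and _s_at differed by 0.28. Among 22 mesenchymal markers 1 rose and 0 fell, likewise 1 when adjusted over the list alone (camera adjusted p = 0.232), and that gene was the transcription factor TWIST1, at 0.89, with 2 higher without LCCTam replicate 3. Of 21 adhesion and junction genes 0 rose and 3 fell, likewise 3 when adjusted over the list alone (camera adjusted p = 0.0554). The desmosome genes DSG2 and DSP differed by -1.17 and -1.03, and the tight junction gene TJP1 by -0.69.

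Growth factor receptors also went both ways. Of 33 receptors and ligands 2 rose and 2 fell, the same numbers when adjusted over the list alone (camera adjusted p = 0.833). RET rose by 2.25, and the fibroblast growth factor receptor gene FGFR4 rose from 8.35 ± 0.06 to 10.36 ± 0.27 (SD, n = 3 each; difference 2.01, adjusted p = 0.000704). IGF1R, the insulin-like growth factor receptor gene, differed by -1.32 (adjusted p = 0.00455) and GFRA1, a coreceptor of RET, by -0.39. GFRA1 was dim in both lines, at 4.29 ± 0.03 in SUM44 and 3.90 ± 0.07 in LCCTam (SD, n = 3 each). With the background unknown, these levels do not tell whether it was expressed. Genes at 8p11-p12, a region amplified in some luminal lines, were shifted downward (22 measured, 0 higher, 4 lower, 6 lower when adjusted over the list alone; median -0.26, camera adjusted p = 0.0109). The camera adjusted p was 0.397 with an estimated correlation, and it was 0.0671 without LCCTam replicate 3. Without the _x_at and _s_at probe sets this list was not shifted. Genes of chromosome 8 as a whole were also lower more often, at 11.5% against 5.64% elsewhere. The list was not compared with the rest of that chromosome, so the shift may not be particular to 8p11-p12. TACC1 differed by -3.77, the metalloprotease gene ADAM9 by -1.28, the histone methyltransferase gene NSD3 by -0.98 and DDHD2 by -0.77.

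In lipid metabolism, the cholesterol synthesis list was shifted downward by camera with few genes passing, and genes of fatty acid synthesis went both ways. Of 18 cholesterol genes 0 rose, 3 fell and 15 did not pass, with 6 lower when adjusted over the list alone (median -0.19, camera adjusted p = 0.0388). The camera adjusted p was 0.765 with an estimated correlation, and it was 0.269 without LCCTam replicate 3. Without that array 5 were lower and the median was -0.11. Without the _x_at and _s_at probe sets the cholesterol list was not shifted. HMGCS1, which makes HMG-CoA, differed by -1.31, and MSMO1 and HSD17B7, enzymes of later steps, by -0.60 and -0.45. Of 15 fatty acid genes 2 rose and 1 fell, with 4 and 1 when adjusted over the list alone (camera adjusted p = 0.649) and likewise 4 and 1 without LCCTam replicate 3. FASN, the fatty acid synthase gene, rose by 1.05 and SREBF1, a transcription factor of lipid synthesis, by 0.82, while the elongase gene ELOVL5 differed by -0.82. Oxidative phosphorylation and TCA cycle genes, which include known targets of the estrogen-related receptors, were not shifted (61 measured, 0 higher, 3 lower, 3 lower when adjusted over the list alone; median -0.02, camera adjusted p = 0.327). ACADM, of fatty acid oxidation, differed by -1.16, SDHA by -0.66 and NDUFS1 by -0.46. In this list 2 genes were higher and 5 lower without LCCTam replicate 3, with a median of 0.045.

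AP-1 transcription factors had 0 of 13 genes passing in limma, and 0 when adjusted over the list alone (median 0.17, and 0.27 without LCCTam replicate 3; camera adjusted p = 0.51). The largest difference was FOSL2 at 0.53 (adjusted p = 0.105). FOSL2 passed without LCCTam replicate 3, at 0.67 (adjusted p = 0.0364), and 2 of the factors were then higher. Of 23 AP-1 responsive genes 1 rose and 5 fell, the same numbers when adjusted over the list alone (camera adjusted p = 0.0554). The AP-1 responsive list was shifted in several other settings, among them the one without the _x_at and _s_at probe sets. GJA1 differed by -4.03, the metalloprotease inhibitor gene TIMP1 by -1.37, the cyclin D1 gene CCND1 by -0.76 and EGR1 by -0.74. Of 28 apoptosis regulators 0 rose and 3 fell, likewise 3 when adjusted over the list alone (camera adjusted p = 0.0554). The death ligand gene TNFSF10 differed by -1.22, its receptor gene TNFRSF10B by -1.19 and PMAIP1, which encodes NOXA, by -1.12. Without LCCTam replicate 3 the adjusted p of TNFSF10 was 0.0538. Of 21 p53 targets 2 rose and 1 fell, the same when adjusted over the list alone (camera adjusted p = 0.833), with PHLDA3 at 0.76, DDB2 at 0.58 and TNFRSF10B at -1.19.

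The remaining lists were not shifted. Of 29 unfolded protein response genes 0 rose and 2 fell, likewise 2 when adjusted over the list alone (median 0.12, camera adjusted p = 0.423), SEL1L at -0.65 and the chaperone gene CANX at -0.53, with 1 higher and 4 lower without LCCTam replicate 3. Of 34 hypoxia and glycolysis genes 1 rose and 1 fell, and 0 passed when adjusted over the list alone (camera adjusted p = 0.833), with the glucose transporter gene SLC2A1 at 0.89 and KDM3A at -0.48. Of 34 drug metabolism genes 1 rose and 2 fell, the same when adjusted over the list alone (camera adjusted p = 0.833). The glutathione transferase gene GSTT1 rose by 0.81, and AKR1C2 and AKR1C1 fell, with 1 higher and 3 lower without LCCTam replicate 3. Of 32 WNT genes 1 rose and 3 fell, the same when adjusted over the list alone (camera adjusted p = 0.833). The ligand gene WNT4 rose by 1.18 (adjusted p = 0.000843), and the receptor genes FZD5, FZD3 and FZD6 differed by -0.96, -0.77 and -0.66. FZD3 and FZD6 were dim, going from 4.76 to 3.99 and from 4.52 to 3.86, where expression cannot be told from background. In this list 2 genes were higher and 3 lower without LCCTam replicate 3. The FZD5 probe set left without the suffixes _x_at and _s_at differed by 0.24.

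Proliferation genes had 0 of 50 passing in limma, and 0 when adjusted over the list alone (median -0.06, and -0.0058 without LCCTam replicate 3; camera adjusted p = 0.51). The largest difference was TOP2A at -0.89 (adjusted p = 0.186). Of 42 ribosomal protein genes 0 passed, and 0 when adjusted over the list alone (camera adjusted p = 0.833), with RPL9 at -0.42 (adjusted p = 0.0509). RPL9 passed without LCCTam replicate 3, at -0.33 (adjusted p = 0.0363), and 1 ribosomal gene was then higher. Among markers of other cell types, 1 of 14 fibroblast genes fell, COL3A1, also 1 when adjusted over the list alone (camera adjusted p = 0.724). Of 18 leukocyte and endothelial genes 0 passed, and 0 when adjusted over the list alone (median 0.08, and 0.05 without LCCTam replicate 3; camera adjusted p = 0.376), with ENG at 0.30 (adjusted p = 0.217).

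**Figure D3:**
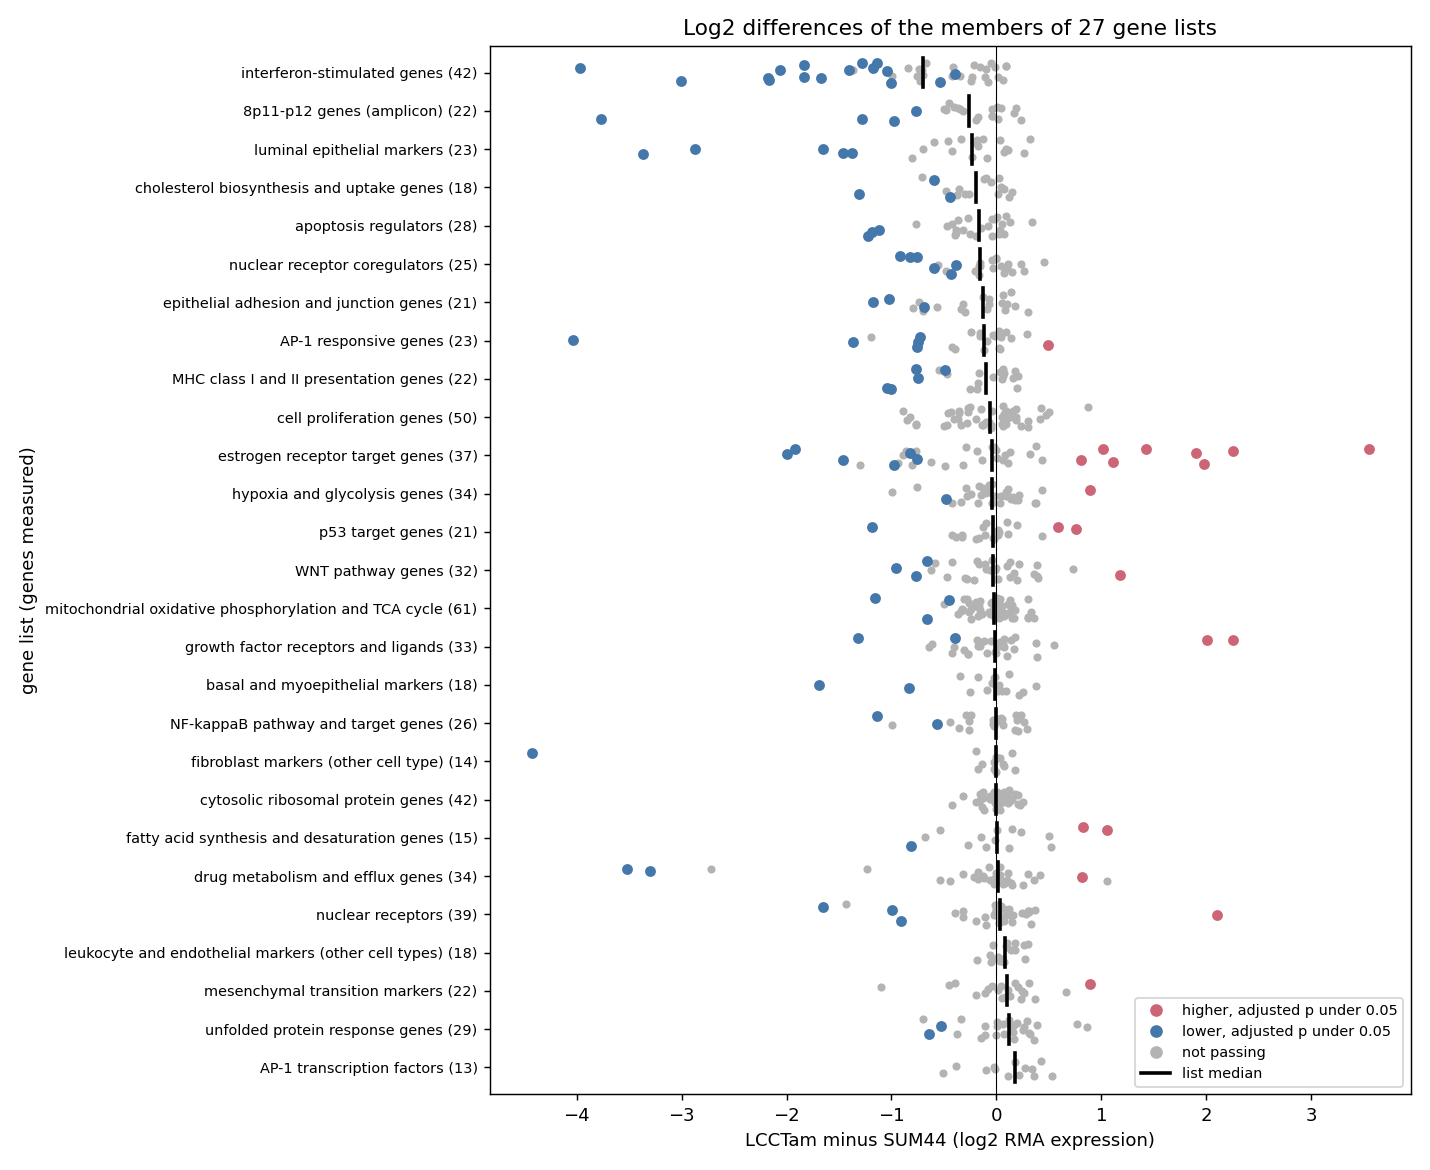
Log2 difference, LCCTam minus SUM44, of every measured member of the 27 gene lists, one point per gene, with a black bar at each list's median. Red and blue points passed an adjusted p of 0.05 as higher and lower, and gray points did not. Interferon-stimulated genes have the lowest median, at -0.70.

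In all, 4 of the 27 lists were shifted by camera with the preset correlation, 0 with an estimated correlation and 1, the interferon-stimulated genes, without LCCTam replicate 3. By fry, which asks whether members move one way on average and not whether they differ from other genes, 6 were shifted. These were the interferon-stimulated, 8p11-p12, AP-1 responsive, coregulator and fibroblast lists, downward, and the mesenchymal list, upward. In the fibroblast list 7 members were higher and 7 lower, with a median of -0.0017. Only 1 of them passed, COL3A1, so this call does not show a fall of the list's members in common.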

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

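The tests of LCCTam replicate 3 below were chosen after the result was seen, and the counts over other splits of the samples were planned.

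Control probe sets, used in no comparison between the lines, set LCCTam replicate 3 apart, where the actin control had a 3' minus 5' difference of 1.92 and the GAPDH control 0.61, the highest of the 6 arrays. Poly(A) spike-ins carry no damage from the cells, and their 3' minus middle difference on this array lay above the range of the other 5 arrays for 2 of 4 spike-ins, dap at 1.90 and thr at 2.64, and not for lys and phe. Over the actin, GAPDH and spike-in controls, 4 of 6 were highest on this array. Loss of the 5' part of cellular RNA as the whole cause, and a labelling reaction that reached less of the 5' part, therefore both stay open, and no biological explanation was tested.

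Hybridization controls, added in fixed amounts after labelling, differed between the lines by 0.34 on the log2 scale, at 9.20 ± 0.06 in SUM44 and 9.54 ± 0.19 in LCCTam (SD, n = 3 each; exact two-sided permutation p = 0.1, the smallest 3 against 3 arrays can give). For 13 of 18 control probe sets all LCCTam values lay above all SUM44 values.

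The 6 samples split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split was the 1 of 10 with 948 genes changed, the highest other being 0. It was likewise 1 of 10 for 255 genes changed 2-fold, highest other 0, and 1 of 10 for the 294 genes of the submitters' selection, highest other 16. Every other split mixes the lines, so the difference between the lines adds to the spread within each group. Low gene counts in those splits were therefore likely in advance, and the contrast with them is no separate support. For the 4 shifted lists, 6 of the 10 splits gave as many, with a highest other of 6.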

How the results depend on the processing

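Quantile normalization between arrays was chosen after seeing the data, and the other alternatives were planned. No paired analysis was possible because the lines share no passage and nothing in the labels ties a sample of one line to one of the other. Leaving out 1 array at a time gave 259 to 1527 changed genes (948 with all arrays), 157 to 296 changed 2-fold (255), 279 to 335 in the submitters' selection (294), 1 to 8 shifted lists (4) and an ESRRG difference of 1.88 to 2.36. The lowest counts of genes came without SUM44 replicate 2. Over all settings the ESRRG difference was 1.64 to 2.36 with adjusted p from 0.000232 to 0.0285, and it has no value without the _x_at and _s_at probe sets, since both of its probe sets are of that kind. Without those probe sets 598 genes changed, 157 of them 2-fold, and 2 lists shifted, the AP-1 responsive and the interferon-stimulated genes. The luminal, 8p11-p12 and cholesterol lists were not shifted without those probe sets. There another probe set stood for COL3A1, TACC1, ALB, TRIM24, ITGB4 and FZD5, which had passed as lower. With it the fall was not seen, and their differences were, in this order, 0.020, 0.089, 0.026, 0.054, 0.28 and 0.24. Beside these 6, 7 other named genes lost the call without those probe sets and kept their direction. Only 53 of the 80 named genes that passed had a value in that setting, so the rest could not be checked there. Array weights gave 3844 changed genes and 1 shifted list. The weights were 4.02 for LCCTam replicate 1 and 2.88 for SUM44 replicate 2, so 1 array counted most in each line. They were 0.64 and 0.83 for SUM44 replicates 1 and 3, and 0.81 and 0.20 for LCCTam replicates 2 and 3. An adjusted p under 0.01 left 279 genes, and a test against a 2-fold change (treat) left 34. Shifted lists numbered 7 with every probe set on its own, 7 with each array's median subtracted, and 0 with an estimated correlation. The cause of the changes with scaling was not tested. The log2 of 10 floor removed no gene and so tests nothing. Of 80 named genes that passed, 44 lost the call without SUM44 replicate 2, 38 without LCCTam replicate 1, 34 without LCCTam replicate 2 and 3 without LCCTam replicate 3. Signal over background could not be judged without detection calls.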

Other observations

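All tests in this part were chosen after the results were seen. For chromosome 4 without LCCTam replicate 3, the prediction was written before that value was seen, but after chromosome 4 genes had been seen lower. Genes named in this part outside the rule for named genes were chosen after their values were seen.

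Genes of chromosome 4 were lower in LCCTam more often than those of other chromosomes. Of 453 genes placed there with the RefSeq table, 89 were lower and 4 higher, so 19.6% were lower, against 5.31% elsewhere (Fisher's exact test, adjusted p = 1.0e-23 over 23 chromosomes; genes are not independent). They included NPY1R, a neuropeptide Y receptor, at -3.03, INPP4B, a phosphoinositide phosphatase, at -2.40, the lysosomal protein gene SCARB2 at -1.96 and TBC1D9 at -1.76. Chromosome 8, with 11.5% lower, and chromosome 2, with 9.80%, also had more lower genes (adjusted p = 3.0e-05 and 4.1e-05). So had chromosome 13, with 9.81%, and chromosome 5, with 8.48% (0.0377 and 0.0347). Chromosomes 22, 16, 19, 17, 9 and X had fewer, with 1.28%, 1.34%, 1.36%, 2.71%, 2.88% and 3.24%.

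The expressed genes of chromosome 4 (those at or above the median level) had a median difference of -0.49 relative to all expressed genes, and the LCCTam replicate 3 array is argued against, since without it this was -0.57. Chromosomes 5 and 13 are AT-rich and 16, 17, 19 and 22 GC-rich, so base composition may account for part of these shares. As the whole cause it is argued against by the size of the difference. The median of chromosome 4 differed from that of chromosomes 5, 13 and 18 by -0.37 (permutation p = 1e-05, the smallest that 100000 permutations can give). From that of chromosome 13 alone it differed by -0.29 (permutation p = 9e-05). Chromosome 4 was picked as low in these same data and genes were shuffled as if independent, so these p-values can be too small. Of 8 consecutive windows of 20 expressed genes, 100% lay below the median of all expressed genes, against 48.2% of 282 windows on other chromosomes. Since chromosome 4 was picked as low over these same genes, low windows were likely in advance and are no separate support for fewer copies. The window medians, from -0.83 to -0.21, show only that the fall was spread along the chromosome. Fewer copies of chromosome 4 in LCCTam may account for the fall, as a hypothesis found and tested on the same data, with no DNA measured here.

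For the fall of interferon-stimulated genes, 3 technical explanations are argued against. The median stayed at -0.55 without LCCTam replicate 3. Leukocyte and endothelial markers had a median of 0.081, where cells of these types in SUM44 would lower it. The list stayed shifted with quantile normalization between arrays, which speaks against a scaling difference. Its median was at percentile 0 of 10000 random lists matched on mean expression, but the list was picked for its low median, so this adds little. A candidate explanation, lower IRF9 and interferon signalling in LCCTam, predicted a fall of a group of MHC class I presentation genes. It was listed as HLA genes, B2M, TAP1, TAP2 and the immunoproteasome subunits, after several of these had been seen lower. The median of this group over 10 measured genes was -0.48, with 5 lower, and -0.38 without LCCTam replicate 3. The 7 outside the interferon list had a median of -0.47, with 3 lower. HLA-B and HLA-C were among the lower genes, and their probe sets can cross-hybridize. Since these genes were not chosen blind to their values, and line, drug and array batch are confounded, this explanation stays open.

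RET and FGFR4 were higher, so genes that respond to the MAPK pathway were listed and tested for a rise. Of 17 measured, 3 were higher, SPRY4 at 1.62, DUSP6 at 0.90 and IER3 at 0.49, and 3 were lower, SPRY1 at -0.97, CCND1 at -0.76 and EGR1 at -0.74. The median was -0.019, and with members going both ways it does not decide whether MAPK output differed.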
